A study of Homo sapiens with 5 samples.

How the data were processed

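Libraries from total RNA of MDA-MB-231 cells were measured in 5 samples, 3 weakly adherent and 2 strongly adherent, separated by shear stress per the labels. RNA was purified with RNeasy columns and checked on a TapeStation, libraries were made with the TruSeq Stranded RNA kit, and 50 bp single-end reads were sequenced on an Illumina HiSeq system, per the labels' protocols. The RNA integrity values themselves are not given in the sources used here, nor is whether messenger RNA was selected by its poly(A) tail or ribosomal RNA was depleted. The submitters' processing notes name cutadapt, FastQC, STAR, HTSeq and DESeq2 and the genome build hg19, without versions. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may be assigned to either, and near-identical gene copies may have lost reads as not unique.

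The authors deposited a table of raw counts per gene symbol and a table of log2 values, both with 25387 rows, of which 25382 are genes and 5 are HTSeq's totals of reads outside genes, ambiguous, of low quality, not aligned or not unique. Those 5 rows stayed out of library sizes and tests. Reads outside annotated genes were 7.96% to 9.84% of uniquely aligned reads, ambiguous reads 1.34% to 1.43%, reads not aligned 1.74% to 3.02% and not unique 16.0% to 16.8% of all rows. The deposited log2 values equal log2(count / size factor + 1) with 1 size factor per library, as tested on the file, where the recovered and the raw counts differ by at most 0.0153 reads. Symbols of 28 rows are spelled like dates, as a spreadsheet leaves them; 21 of them were tested, 1 was called, and none is named. Gene counts per library ran from 19630386 to 21707459.

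Samples were grouped by the adhesion label. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit and F test, Benjamini-Hochberg adjusted p under 0.05) on the deposited raw counts, and a log2 fold change is weakly minus strongly adherent. Standard errors follow from the fold change and the F statistic. CPM values are scaled by TMM and given as mean ± SD. The biological coefficient of variation was 7.91%, with 3 residual degrees of freedom. Of 27 gene lists fixed before the data were examined, 25 with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move without comparing them with other genes, were alternatives. In lists, genes were also adjusted over the list alone. The results of 1 list and of 2 named genes are not reported here. Shares of counts were compared by a two-sided exact permutation test. The 4 libraries of 6 and 15 March were also compared between those dates, with adhesion as a covariate.

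Libraries of the 2 groups that carry the same date were taken as pairs, because the titles give the date. Their deviations from the group means correlated at 0.34 on 6 March and 0.20 on 15 March. The weakly adherent library of 12 March correlated at -0.16 and 0.16 with the strongly adherent ones of 6 and 15 March. With 2 strongly adherent libraries their deviations mirror each other, so these values are not independent and speak only weakly for the pairing. The fit with the date as a block is an alternative to the fit without it, and in it the weakly adherent library of 12 March carries no weight and 1 residual degree of freedom is left. No 2 replicates agreed within sampling noise: chi-square per degree of freedom between replicates of a group was 7.19 to 12.0. The log2 CPM of replicates correlated at 0.9936 to 0.9945 across genes, and between groups at 0.9902 to 0.9931.

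The genes named by a rule fixed before the data were examined are the 10 with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 2 CPM and no overlap between the groups' libraries; from each list the 2 tested members with the smallest p; always ITGB1, ITGA5, VCL, PXN, TLN1, VIM, CD44, MKI67 and CDH1; and, between the dates, the 3 genes with the smallest p in each direction with a mean of at least 2 CPM.

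Alternatives fixed before the data were examined were DESeq2's size factors, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 2 libraries, the date block in edgeR and as a random effect in limma-voom, the authors' log2 values (pseudocount 1, and recomputed with 5), each library left out in turn, and, for shares, the total without the 10 most abundant genes. DESeq2's size factors moved the median log2 fold change of all genes by -0.0026. Removing the trend of each library with transcript length, GC content or coding length (a natural spline with 5 degrees of freedom, as an offset) was added after the data were seen, as were the date block with each. Transcript and coding lengths and GC content were taken by gene symbol from GENCODE release 29, which is annotated on another build than the authors used and served for no coordinates. The length is that of the longest transcript, and 12417 of the tested genes (93.4%) and 95.8% of the called ones had one. Which transcript the cells expressed is not known.

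The tests were tried on simulated data: counts for the 13297 genes were drawn 10 times from the libraries' means, sizes and dispersions with 200 genes changed, 100 by 1.5-fold and 100 by 2-fold. With gene-wise dispersions edgeR recovered 67.1% of the genes changed 1.5-fold and 86.6% of those changed 2-fold, all recovered ones in the right direction, and 9.56% of its calls were unchanged genes, against 17.5% with the date block. With dispersions on the trend these shares of unchanged genes were 6.01% and 5.94%. No date effect was simulated, so these shares do not show how the fits with and without the block compare where dates differ. A simulated length trend with no changed gene gave 273 calls, and 3 after the trend was removed. With 1 simulated list shifted, camera called 1 list with the preset and 0 with an estimated correlation. Genes were drawn independently of each other there, while the estimate for G2/M genes in the real libraries was 0.75. That run therefore cannot tell which correlation suits the real lists. Figures were drawn with matplotlib 3.10.9.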

Results

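The study asked how cells of 1 tumour line that differ in how firmly they hold to a surface differ in gene expression. MDA-MB-231, a human triple-negative breast cancer line of mesenchymal character, was separated by shear stress into weakly and strongly adherent populations. Sequencing libraries were made from total RNA of 3 weakly adherent samples, dated 6, 12 and 15 March, and of 2 strongly adherent samples, dated 6 and 15 March. Each library held between 19630386 and 21707459 reads assigned to genes, the fewest in the weakly adherent library of 12 March. Of 25382 genes, 13297 had enough reads to be tested. The labels do not say whether the samples came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical. The shear separation defined the groups, so a response to it cannot be told apart from a difference that the cells had before.

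Adhesion was the strongest axis of variation among the 5 libraries. The first principal component, with 39.2% of the variance, separated the 3 weakly adherent libraries from both strongly adherent ones. The second, with 28.8%, separated the 2 libraries of 6 March from those of 12 and 15 March.

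**Figure D1:**
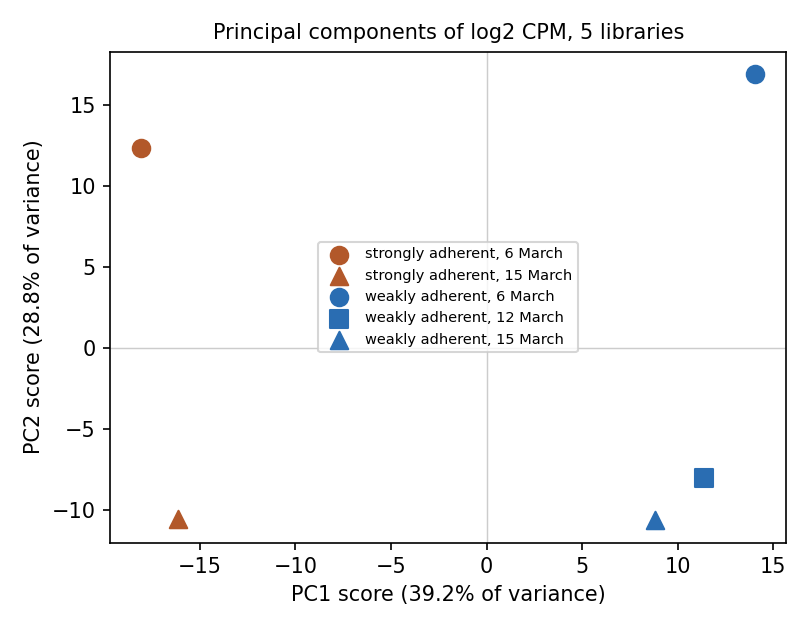
Principal component scores of the 5 libraries from log2 CPM of the tested genes, with PC1 on the x axis (39.2% of the variance) and PC2 on the y axis (28.8%). Colour gives the adhesion group and marker shape the date. The weakly adherent libraries lie at PC1 scores of 8.79 to 14.1 and the strongly adherent ones at -18.1 and -16.2.

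Weakly adherent cells had more RNA of G2/M genes and of genes with very long coding sequences, and less RNA of S phase genes, YAP/TEAD targets and some cytokines. With an estimated correlation camera called 0 of the 25 gene lists, at adjusted p = 0.36 for G2/M genes, 0.26 for S phase genes, 0.26 for YAP/TEAD targets and 0.28 for NF-kB targets and cytokines. With edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 235 genes were higher and 122 were lower in the weakly adherent cells, and 1889 genes had an unadjusted p under 0.05. All 357 called genes had the same sign in the pairs of 6 and of 15 March, as the test that selected them favours. Over all 13297 genes tested, the 3 weakly adherent libraries lay on 1 side of both strongly adherent ones in 3987. Chance gives 20% for a single gene, but genes move together, so this count is no test of adhesion. The changes were mostly moderate: the median absolute log2 fold change of the called genes was 0.54, and 42 genes changed by at least 1, of which 31 were higher and 11 lower.

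Among called genes with a mean of at least 2 CPM, those with the largest increases included mitotic regulators and giant structural proteins. ASPM, which organises spindle poles, rose from 65.5 ± 5.64 CPM (SD, n = 2) to 194 ± 33.1 CPM (SD, n = 3), a log2 fold change of 1.57 (SE 0.14, edgeR adjusted p = 0.0014). The kinetochore motor CENPE rose 2.59-fold, the kinetochore protein CENPF 2.32-fold and the actin and microtubule linker GAS2L3 2.39-fold. SYNE2, the nuclear envelope spectrin repeat protein that ties the nucleus to the cytoskeleton, rose from 17.4 ± 2.71 to 48.5 ± 7.35 CPM (log2 fold change 1.47, SE 0.14, edgeR adjusted p = 0.00067). AHNAK, a giant scaffold protein, rose from 621 ± 91.3 to 1452 ± 181 CPM (log2 fold change 1.23, SE 0.12), and EXPH5, a Rab27 effector, rose 2.56-fold. With the trend with coding length removed, the log2 fold change was 0.60 for SYNE2 (coding sequence of 20721 bases) and 0.45 for AHNAK (17670 bases), and both calls stood (adjusted p = 0.0037 and 0.0099). The pro-apoptotic gene BMF and the non-coding RNAs KCNQ1OT1 and LINC00342 rose 2.59-fold, 2.51-fold and 2.39-fold at low levels of 2.87 to 6.08 CPM in weakly adherent cells. KCNQ1OT1, whose annotated transcript has 91667 bases, had a log2 fold change of 0.06 (adjusted p = 0.96) with the trend with transcript length removed, or 0.16 (0.73) with the date block as well. The trend removed from it was far larger than 0.20, the median of the 518 genes with transcripts over 10 kb. Its lost call therefore does not show that length accounts for its rise. Without the strongly adherent library of 6 March the calls on these 3 ended, at adjusted p = 0.13, 0.11 and 0.14. Those on KCNQ1OT1 and LINC00342 also ended without the strongly adherent library of 15 March (0.10 and 0.12), and that on LINC00342 without the weakly adherent library of 15 March (0.066).

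Among called genes with a mean of at least 2 CPM, the largest decreases were headed by the tight junction protein CLDN1. CLDN1 fell from 4.62 ± 0.34 to 1.97 ± 0.26 CPM (log2 fold change -1.23, SE 0.20, edgeR adjusted p = 0.0053). The long non-coding RNA UCA1 was 2.21-fold lower (24.9 ± 1.30 against 11.2 ± 0.69 CPM) and the protease inhibitor SERPINB2 2.21-fold lower. The Wnt antagonist DKK1 fell from 303 ± 3.88 to 160 ± 17.8 CPM (log2 fold change -0.92, SE 0.09, edgeR adjusted p = 0.00019), and ANKRD1, a YAP target, fell from 286 ± 20.8 to 147 ± 5.24 CPM (log2 fold change -0.96, SE 0.07). The chemokine CXCL1, the receptor kinase MUSK, the interleukin-7 receptor chain IL7R, the activin antagonist FST and complement C3 were 2.12-fold, 1.85-fold, 1.82-fold, 1.72-fold and 1.72-fold lower. Each of those 5 calls ended when 1 library was left out: the highest adjusted p with 1 library left out was 0.15 for CXCL1 and 0.058 for IL7R (both without the strongly adherent library of 15 March), and 0.19 for MUSK, 0.12 for FST and 0.15 for C3 (each without the strongly adherent library of 6 March).

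The counts depended on how the libraries were paired and on single libraries. With the shared date as a block, edgeR called 808 genes higher and 709 lower, all 357 calls without the block among them, and limma-voom with the date as a random block called 670 and 538. The block leaves 1 residual degree of freedom. Without the strongly adherent library of 6 March the counts were 82 higher and 34 lower, without the weakly adherent library of 12 March 138 and 56, without the strongly adherent library of 15 March 50 were lower, and without the weakly adherent library of 15 March 67 were lower. Of the 41 named genes with a call, 21 kept it whichever library was left out.

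The increases followed coding length. Among genes with a coding sequence over 10 kb, the median log2 fold change was 0.72 (76 genes, 92.1% of them positive, 41 called higher and 0 lower), which corresponds to 1.65-fold. The median was 0.42 for 8 to 10 kb (72 genes, 38 called higher), 0.21 for 6 to 8 kb (179 genes, 30 called higher) and 0.12 for 4 to 6 kb (565 genes), and lay between -0.02 and 0.03 in each class under 4 kb. Genes with a coding sequence over 6 kb thus supplied 109 of the 216 higher calls with a known coding length and 1 lower call. For genes over 10 kb the pair of 6 March gave a median of 0.80 and the pair of 15 March 0.72. Against the mean of all libraries, these genes lay at -0.52 in the strongly adherent library of 6 March, -0.32 in that of 15 March, and 0.28, 0.17 and 0.37 in the weakly adherent libraries of 6, 12 and 15 March. With the trend with coding length removed from each library, a setting chosen after the data were seen, edgeR called 105 genes higher and 128 lower, or 531 and 674 with the date block. With the trend with transcript length removed the split was 161 higher and 151 lower, or 620 and 736 with the date block.

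**Figure D2:**
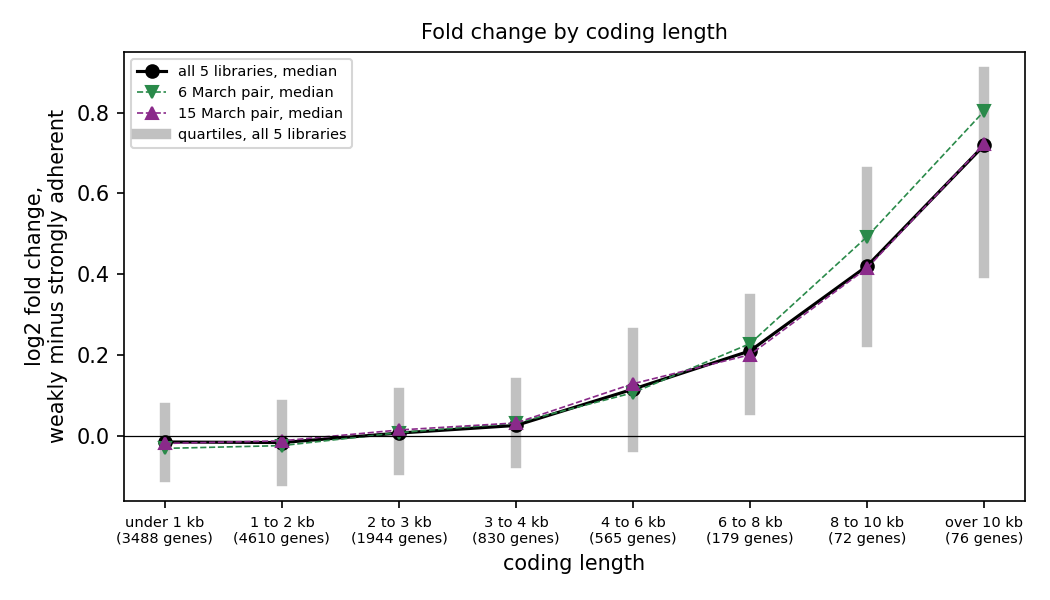
Median log2 fold change of weakly minus strongly adherent cells (y axis) in 8 classes of coding length (x axis, number of genes below each), over all 5 libraries and in the pairs of 6 and 15 March alone. Grey bars are the quartiles over genes. The median rises from -0.01 in genes under 1 kb to 0.72 in genes over 10 kb.

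Genes of the G2 and M phases of the cell cycle were higher in weakly adherent cells. Of 56 G2/M genes, 14 rose over all genes tested and 43 adjusted over the list alone, 0 fell, and 54 had a positive log2 fold change, with a median of 0.50. With the date block, 44 rose. MKI67, the proliferation antigen, rose from 457 ± 3.02 to 889 ± 136 CPM (log2 fold change 0.96, SE 0.12, edgeR adjusted p = 0.0021). ASPM, which is not on the list, and the members CENPE, CENPF and MKI67 have coding sequences of 10431, 8103, 9342 and 9768 bases. With the trend with coding length removed, the log2 fold changes of ASPM, CENPE and CENPF were 1.11, 1.04 and 0.81 and their calls stood, that of MKI67 was 0.53 (adjusted p = 0.062, or 1.3e-10 with the date block), and the list's median was 0.49 with 11 of 54 members called higher. Camera called the list higher with a preset correlation (adjusted p = 3.9e-44), at adjusted p = 0.36 with an estimated correlation.

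Genes of the S phase were lower. Of 43 S phase genes, 16 fell over all genes tested and 33 adjusted over the list alone, all 43 had a negative log2 fold change, and the median was -0.28. With the date block, 36 fell. The replicative helicase subunit MCM6 fell from 177 ± 2.36 to 115 ± 6.55 CPM (log2 fold change -0.62, SE 0.07, edgeR adjusted p = 0.00076), and UNG, the uracil glycosylase of base excision repair, was 1.44-fold lower. Camera called the list lower (adjusted p = 4.5e-28), at adjusted p = 0.26 with an estimated correlation. Replication-dependent histone genes were not called (0 of 14 members, camera adjusted p = 0.71, 0.99 with an estimated correlation). They had few reads in these libraries, 0.0129% ± 0.00081 of counts (SD, n = 3) in weakly and 0.0133% ± 0.00076 (SD, n = 2) in strongly adherent cells. The absence of calls therefore says little about histone messages or about S phase.

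**Figure D3:**
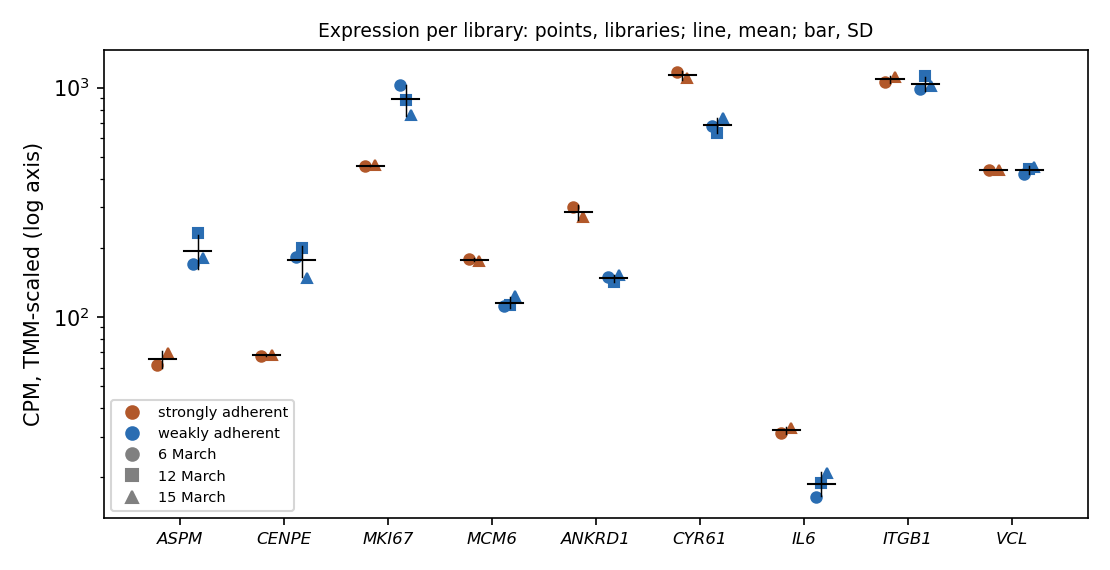
TMM-scaled CPM (y axis, log scale) of 9 genes in each of the 5 libraries. Points are libraries coloured by adhesion group with the marker giving the date, horizontal lines are group means and vertical bars the SD. ASPM, CENPE and MKI67 are higher and MCM6, ANKRD1, CYR61 and IL6 lower in every weakly adherent library, while ITGB1 and VCL overlap.

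Targets of YAP and TEAD, transcription regulators that respond to cell spreading and tension, were lower as a group. Of 22 YAP/TEAD targets, 9 fell and 1 rose over all genes tested, with the same counts adjusted over the list alone, and the median log2 fold change was -0.13. Besides ANKRD1, CYR61 fell from 1131 ± 47.4 to 685 ± 50.3 CPM (log2 fold change -0.72, SE 0.08, edgeR adjusted p = 0.00057). Camera called the list lower (adjusted p = 4.9e-11), at adjusted p = 0.26 with an estimated correlation, and it was 1 of 3 lists that fry called (adjusted p = 0.034, or 0.18 with the date block). Immediate early genes, which respond within minutes to growth factors and stress, fell in 4 of 25 members (2 higher and 5 lower adjusted over the list alone, 1 and 8 with the date block), among them HBEGF (1.37-fold lower) and the phosphatase DUSP1 (1.51-fold lower, adjusted p = 0.14 without the strongly adherent library of 6 March). Camera gave adjusted p = 0.0022 and fry 0.020, against adjusted p = 0.26 with an estimated correlation and 0.21 for fry with the date block. Whether the YAP/TEAD and immediate early changes came before or with the shear separation cannot be told from these samples.

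Some cytokine genes were lower. Of 23 NF-kB targets and cytokines, 3 fell over all genes tested, 6 adjusted over the list alone and 12 with the date block, and 22 had a negative log2 fold change (median -0.25). Interleukin-6, IL6, fell from 32.0 ± 1.20 to 18.7 ± 2.24 CPM (log2 fold change -0.77, SE 0.11, edgeR adjusted p = 0.0022). Camera called the list lower (adjusted p = 8.0e-09), at adjusted p = 0.28 with an estimated correlation. Of 29 interferon response genes, 24 had a negative log2 fold change (median -0.17) and none passed over all genes or adjusted over the list alone in edgeR, while 11 fell with the date block. ISG15 had a log2 fold change of -0.31 (adjusted p = 0.16) and HERC5 one of -0.29 (adjusted p = 0.14). Camera called that list lower (adjusted p = 7.0e-05), at adjusted p = 0.80 with an estimated correlation.

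Few of the genes that build adhesions passed the test. Of 14 integrins, 0 passed over all genes or adjusted over the list alone, and 1 was higher and 2 lower with the date block. The median log2 fold change was -0.01 (camera adjusted p = 0.91, 0.99 with an estimated correlation). The integrin chains ITGB1 (1088 ± 40.8 against 1042 ± 74.6 CPM, log2 fold change -0.06, SE 0.08) and ITGA5 (0.02, SE 0.07) did not differ by more than the spread between libraries. The same held for the focal adhesion proteins vinculin (VCL, 0.0023, SE 0.07) and paxillin (PXN, -0.05, SE 0.08), and for CDH1 (-0.30, SE 0.29). The libraries of the groups did not overlap for talin (TLN1, 686 ± 7.56 against 720 ± 6.69 CPM, log2 fold change 0.07, SE 0.07), CD44 (1655 ± 58.3 against 1500 ± 25.8 CPM, -0.14, SE 0.07) and VIM (2699 ± 66.7 against 2554 ± 85.1 CPM, -0.08, SE 0.08), but none of these 3 passed edgeR's test (adjusted p = 0.77, 0.44 and 0.76). TLN1, whose coding sequence has 7623 bases, turned to -0.24 (adjusted p = 0.18) with the trend with coding length removed, and to -0.26 (adjusted p = 0.0025) with the date block as well, a fit with 1 residual degree of freedom. Of 36 focal adhesion genes 1 fell (1 higher and 3 lower adjusted over the list alone, 2 and 8 with the date block), the adaptor FHL2 (1.27-fold lower, adjusted p = 0.049, and 0.46 without the strongly adherent library of 6 March). Camera gave adjusted p = 0.056 for the list and 0.79 with an estimated correlation, and fry's test for change in either direction 0.016. Camera called the list lower without the strongly adherent library of 15 March (0.019), without the weakly adherent library of 6 March (0.031) and with the trend with coding length removed (0.00064).

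Matrix genes went both ways. Of 35 matrix and protease genes 1 rose and 2 fell (3 and 2 adjusted over the list alone, 3 and 8 with the date block). The laminin chain LAMA5, with a coding sequence of 11085 bases, rose 1.40-fold, and its log2 fold change was -0.02 (adjusted p = 0.98) with the trend with coding length removed and 0.46 (adjusted p = 0.069) without the strongly adherent library of 6 March. Camera did not call the list (adjusted p = 0.80, 0.99 with an estimated correlation), while fry's test for change in either direction did (adjusted p = 2.7e-05), and camera called it lower with the trend with coding length removed (adjusted p = 9.4e-07).

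Microtubule genes were called higher by camera (adjusted p = 0.032, 0.79 with an estimated correlation). Fry's test for change in either direction gave adjusted p = 0.0037. Of 37 microtubule genes 2 rose over all genes tested, 3 adjusted over the list alone and 8 with the date block. Both that rose are long: the dynein heavy chain DYNC1H1 (1.73-fold, coding sequence of 13938 bases) and MAP1B (1.62-fold, 7404 bases). With the trend with coding length removed, DYNC1H1 had a log2 fold change of 0.16 (adjusted p = 0.47), MAP1B stayed called at 0.41 (adjusted p = 0.020) and the list was not called (adjusted p = 0.50). The list call also ended without the strongly adherent library of 6 March (adjusted p = 0.11) or the weakly adherent library of 6 March (0.16). Ribosomal protein genes were called higher by camera (adjusted p = 0.0095, 0.99 with an estimated correlation) with a median log2 fold change of 0.06 and 0 of 71 members called over all genes or adjusted over the list alone in edgeR, and 6 called with the date block. That call ended without the strongly adherent library of 15 March (adjusted p = 0.94) or the weakly adherent library of 6 March (0.58).

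The lists described next did not pass camera's test with all 5 libraries. Mesenchymal (10 tested) and epithelial (17 tested) markers had medians of -0.06 and 0.0030, with 0 members called over all genes, and 1 higher and 1 lower adjusted over each list alone. Fry's test for change in either direction gave adjusted p = 0.0015 for the mesenchymal and 0.065 for the epithelial list, and 0.0041 for the ATF4 list. The members passing over their list alone moved in both directions. Of the mesenchymal list SNAI1 had a log2 fold change of 1.28 at 1.98 CPM in weakly adherent cells (edgeR adjusted p = 0.078, or 0.0065 with the date block) and TGFBI -0.30 (0.089, or 0.000043). Of the epithelial list ELF3 had 0.87 (0.058, or 0.00083) and KRT7 -0.31 (0.074, or 0.0022). Heat shock genes (19 tested) and endoplasmic reticulum chaperones (20 tested) had 0 members called over all genes or adjusted over the list alone. The ATF4 (27 tested), hypoxia (29), cholesterol (25), respiratory chain (29) and p53 (14) lists had camera adjusted p of 0.89, 0.80, 0.98, 0.099 and 0.80. Single members passed over all genes tested, and adjusted over the list alone the ATF4 and respiratory chain lists had 1 higher, the hypoxia list 2 higher and 1 lower and the p53 list 1 lower: the cystine transporter SLC7A11 rose 1.46-fold (ATF4 list), VEGFA rose 1.32-fold and ADM was 1.34-fold lower (hypoxia list), COX7A2 rose 1.25-fold (respiratory chain list) and CDKN1A was 1.28-fold lower (p53 list). Each of these 5 calls ended without the strongly adherent library of 6 March (adjusted p = 0.069 for SLC7A11, 0.21 for VEGFA, 0.25 for ADM, 0.097 for COX7A2 and 0.52 for CDKN1A). The respiratory chain list, at camera adjusted p = 0.099 and adjusted p = 0.99 with an estimated correlation, was called higher without the strongly adherent library of 6 March (0.0039), without the weakly adherent library of 15 March (0.035) and with the trend with coding length removed (0.036).

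Mitochondrially encoded messengers made up 4.15% ± 0.60 of counts (SD, n = 3) in weakly and 4.2% ± 0.97 (SD, n = 2) in strongly adherent cells (exact permutation p = 0.80, two-sided; 0.10 is the smallest p that 3 against 2 libraries allow, and 0.90 adjusted over 8 shares). Camera did not call the list (adjusted p = 0.98, 0.99 with an estimated correlation), but with the preset correlation called it higher without the strongly adherent library of 6 March (7.6e-05) and lower without that of 15 March (0.00040). Reads outside annotated genes made up 9.28% ± 0.49 of uniquely aligned reads in weakly and 8.43% ± 0.65 in strongly adherent cells (exact permutation p = 0.10, and 0.80 adjusted over 8 shares).

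**Figure D4:**
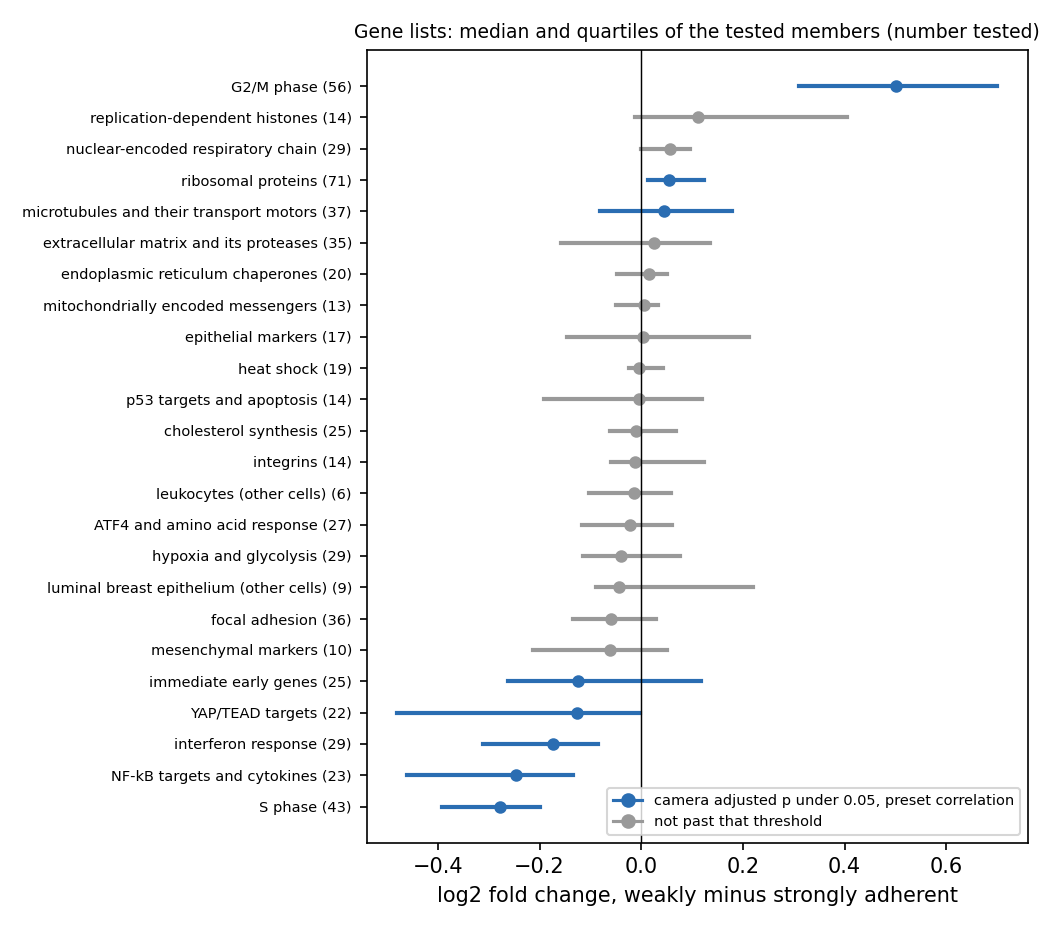
Median (point) and quartiles (line) of the log2 fold change, weakly minus strongly adherent (x axis), over the tested members of each of 24 gene lists (number tested in parentheses). Blue lists had a camera adjusted p under 0.05 with the preset correlation, from G2/M phase with a median of 0.50 to S phase with -0.28, and with an estimated correlation 0 lists did.

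The titles' dates allowed a second contrast, 15 against 6 March, with adhesion as a covariate in the 4 libraries of those days. Transcripts of the secretory pathway genes TMED7, a cargo receptor, and SRP9, a subunit of the signal recognition particle, were higher on 15 March: TMED7 rose from 45.1 ± 2.98 to 98.7 ± 13.3 CPM (SD, n = 2 each; log2 fold change 1.13, SE 0.07, edgeR adjusted p = 1.2e-46) and SRP9 by 1.07 on the log2 scale. The glia maturation factor GMFB rose by 0.88. The chaperone HSPA8 fell from 3464 ± 524 to 2287 ± 87.2 CPM (log2 fold change -0.59, SE 0.07), the mitochondrial gene ND1 had a log2 fold change of -0.56 and the mitotic kinase AURKA one of -0.51. In all, edgeR called 1231 genes, 893 higher and 338 lower on 15 March, with 1 residual degree of freedom, and DESeq2's Wald test called 205. Camera called mitochondrially encoded messengers (median log2 fold change -0.37), G2/M genes (-0.29), heat shock genes (-0.14) and ribosomal proteins (-0.14) lower on 15 March, and cholesterol synthesis (0.15) and interferon response genes (0.16) higher. S phase (0.06), integrin (0.18), matrix (0.09) and leukocyte marker lists (0.20) were also called higher and the respiratory chain list (-0.08) lower. Each of these 11 calls had an adjusted p = 0.70 with an estimated correlation. Genes with a GC content under 40% had a median log2 fold change of 0.16 between the dates, and those over 60% one of -0.03. What the dates mark, such as the isolation or the library preparation, is not given in the sources used here.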

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

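The tests on transcript length within the G2/M list and on RNA integrity, the classes by coding length and GC content, and the counts of date calls that stayed without a trend, were chosen after the results were seen, and the other tests in this part before. Reads outside annotated genes are data that no comparison of genes uses, and their share of uniquely aligned reads was 0.853 percentage points higher in weakly than in strongly adherent libraries (exact permutation p = 0.10, the smallest that 3 against 2 libraries allow, and 0.80 adjusted over 8 shares).

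Long messages were higher in weakly adherent cells, with a median log2 fold change of 0.20 over the 518 genes with transcripts over 10 kb. A bias that follows annotated transcript length alone is argued against: among 1032 coding genes with transcripts over 8 kb, those with the larger coding share had a median 0.20 above those with the smaller one (0.24 against 0.04, with annotated transcripts of similar length; permutation p over genes = 1e-05, the smallest that the resamples can give). The median coding lengths were 6033 and 1695 bases. Which transcripts the cells expressed is not known, so the test does not cover a bias with expressed length. GC content as the whole cause is argued against too, since with its trend removed the median over 10 kb was 0.18 with 71.2% of genes above 0. Without the members of the cell cycle lists the median was 0.19, with 74.2% above 0. That step left 515 of the 518 genes, too few removed for the median to move much. It therefore cannot decide whether the cell cycle moves long genes outside those lists. What also stays open is that RNA of the strongly adherent samples may have been less intact. Genes with coding sequences over 10 kb lay apart by 0.70 between the groups and by at most 0.20 between libraries of 1 group. With every strongly adherent sample handled as such, a difference in RNA quality cannot be told apart from one in the cells. Among genes with coding sequences over 6 kb, the median also fell with GC content, from 0.47 under 45% to 0.15 over 55%.

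G2/M genes were higher and S phase genes lower in weakly adherent cells. Transcript length does not account for it, because the 26 G2/M members with transcripts under 3 kb had a median log2 fold change of 0.61, above 0.04, the upper percentile limit of length-matched random lists. A candidate explanation is a shift of cell cycle phases between the populations, towards G2 and mitosis in the weakly adherent one. It predicted that mitotic genes outside the list would be higher and G1/S genes outside the S phase list lower, and their medians were 0.42 (33 genes, 4 called higher) and -0.21 (26 genes, 4 called lower). On 6 and 15 March the medians were 0.47 and 0.23 for the mitotic genes and -0.21 and -0.23 for the G1/S genes. Another cause that moves these programmes as a whole would give the same, so the outcome does not single out a phase shift. With an estimated correlation the camera adjusted p of these 2 added lists was 0.12 and 0.024. None of the 25 lists fixed earlier passed, but they were adjusted over those 25 without the 2 added ones. The adjusted p of the added and of the fixed lists therefore cannot be set side by side. Phases were not measured by another method.

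The 4 libraries of 6 and 15 March differed in 1231 genes. Removing the trend with GC content left 1206 genes called and removing the trend with transcript length 1275. Of the 1175 called genes with a known length, 760 stayed called in the same direction without the GC trend and 946 without the length trend, which argues against either trend as the whole cause. Without the GC trend, 452 of 853 genes higher on 15 March and 308 of 322 lower ones stayed called. With new calls included, 523 were then higher and 683 lower, against 893 and 338 before. Whether the GC trend accounted for part of the date difference was not tested. A difference in handling on the 2 days and one in the cells cannot be separated, since all libraries of a date share both. No biological explanation was tested.

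The 3 against 2 grouping has 10 splits, too few for a share under 0.05: the real grouping called 357 genes, 1 of the 10 splits called as many, and the highest of the others called 55, with the 2 libraries of 6 March against the rest.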

How the results depend on the processing

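Of the alternatives, those that remove a trend with length, GC content or coding length were chosen after the data were seen. Genes higher in weakly adherent cells numbered 235; with the date block 808, with a random date block 670, with the block and the length, GC or coding length trend removed 620, 881 and 531, with the coding length trend alone removed 105, and 82 to 238 with 1 library left out. Genes lower numbered 122; with the same blocks 709 and 538, with block and trend removed 736, 919 and 674, with no low-count filter 203, with the GC trend removed 190, and 34 to 103 with 1 library left out. Leaving out a library leaves fewer samples; otherwise the cause was not tested. The share of higher among called genes was 65.8%, 53.3% with the block, 51.6% with the length trend and 45.1% with the coding length trend removed. Of the 357 calls, 187 of 333 with a coding length stayed called with that trend removed and 6 changed sign. DESeq2 called 296 and 136, limma-voom 222 and 112, with 340 and 331 of the calls kept.

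Camera called 3 lists higher and 6 lower. With an estimated correlation 0 and 0 were called, with fry 0 and 3, with fry and the date block 0 and 0, and with 1 library left out 1 to 4 higher and 5 to 8 lower. The block changed no camera call. Between the dates, a fit of all 5 libraries called 1274 and DESeq2 205 genes against 1231 by edgeR (the cause was not tested). Among single genes and lists, 1681 comparisons with an alternative kept direction and side of the threshold, 118 lost and 122 gained it, 59 without a call changed sign, and 4 with a call before or after reversed: LAMA5 to -0.020 and -0.030 (coding length trend removed, without and with block), TLN1 to -0.26 (with block) and the mitochondrially encoded list to adjusted p = 7.6e-05 without the strongly adherent library of 6 March (7.6e-05 to 0.80 with 1 library left out). In simulated data at this depth edgeR recovered 67.1% of changes of 1.5-fold and 86.6% of changes of 2-fold, so smaller changes are missed more often.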

Other observations

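Of luminal breast epithelial markers 9 were tested and 1 was called over all genes and adjusted over the list alone, AGR2, a secreted disulfide isomerase, which rose from 6.01 ± 0.24 CPM (SD, n = 2) to 12.6 ± 2.99 CPM (SD, n = 3; log2 fold change 1.06, SE 0.19, edgeR adjusted p = 0.013). Without the strongly adherent library of 6 or of 15 March the call on AGR2 ended, at adjusted p = 0.12 and 0.065. Of leukocyte markers 6, of fibroblast markers 4 and of endothelial markers 3 were tested, and 0 were called over all genes in edgeR. With the date block, COL1A2 (log2 fold change -0.82, adjusted p = 1.4e-05) and ROBO4 (-0.43, 0.00085) were called lower and COL1A1 (0.42, 0.014) and the luminal marker CA12 (0.42, 0.0028) higher, so that markers of fibroblasts went both ways. The most abundant of these markers were CD74 at 313 CPM and KRT19 at 274 CPM on average over the 5 libraries.

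Along the genome no chromosome stood apart: the median log2 fold change by chromosome lay between -0.049 and 0.049.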
